A study of Drosophila melanogaster with 6 samples.

How the data were processed

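Gene expression was measured on 6 one-colour arrays with total RNA from sorted cells of Drosophila melanogaster. Groups were taken from the sample labels, as 4 arrays of the fluorescent fraction from cultured embryonic cells (EC_pos), 1 array of the fluorescent fraction from the larval brain and ventral nerve cord (LB_pos) and 1 array of the non-fluorescent fraction of that tissue (LB_neg). The authors deposited 1 intensity per probe set and array, on a linear scale, for 14010 probe sets. The software and algorithm behind these values, the array scanner and any genome build are not given in the sources used here. In the deposited intensities the mean without the lowest and highest 2% of probe sets was between 500.063 and 500.083 on every array, so the values had already been scaled per array and were used without further scaling. No array held the values of another, with at most 18 of 13966 intensities identical between any 2 arrays.

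The 44 control probe sets were left out of all tests and served only to compare arrays, by the ratio of 3' to 5' probe sets of 3 transcripts and the geometric mean of 9 hybridization controls. Intensities were transformed as log2(intensity + 53.6), where 53.6 was the 25th percentile over all 6 arrays. Probe sets above the pooled median of 197.35 on at least 1 array were tested, 9635 of 13966. Between 71.8% (LB_neg) and 79.2% (LB_pos) of probe sets lay above the offset. The number of arrays limits the precision, and no depth applies to arrays.

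Genes were named from the platform's annotation table, updated through locus tags and sequence accessions of the current RefSeq annotation (Release 6 assembly), which was used only for names. Of the 13966 probe sets, 12443 had 1 gene, 327 had several and were left unnamed, and 1196 had none in that table. The symbol was updated for 12394. This gave 10844 genes, 1209 of them with more than 1 probe set, and each gene was represented by the probe set with the highest mean over the 6 arrays. Of these genes 7890 were tested. The files name no genome build, so no coordinates are given.

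Group means were fitted with limma 3.58.1 in R 4.3.3 as a model of 3 means, followed by eBayes with a trend of variance on mean intensity and Benjamini-Hochberg adjustment per contrast, with calls at an adjusted p under 0.05. All adjusted p-values of probe sets are from limma. The residual degrees of freedom, 3, came from the EC_pos arrays alone (prior degrees of freedom 3.74), and the lone larval arrays were assumed to vary like them. Contrasts were EC_pos minus LB_pos and EC_pos minus the mean of both larval arrays. LB_pos and LB_neg were compared by the difference of their log2 values, with counts of probe sets at least 1 log2 unit apart beside the same counts for the 6 pairs of EC_pos arrays. The contrast of EC_pos with LB_pos and the larval contrast share the LB_pos array. The position of each EC_pos array between the larval arrays was a slope across probe sets.

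A total of 28 gene lists were fixed, covering GABA metabolism and receptors, cholinergic, glutamate and monoamine genes, acetylcholine receptors, neuropeptides and their processing, general neuron genes, ion channels, neuroblasts, cell cycle, glia, muscle, hemocytes, fat body, epidermis, eye, germ line, heat shock and dissociation response, antimicrobial peptides, ecdysone response, Hox genes, neuronal identity factors, axon guidance, ribosomal proteins, oxidative phosphorylation and glycolysis. Some genes stand in 2 lists. They were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. Members were counted over all probe sets and adjusted over the list alone. For the larval pair a list's median was placed among 10000 random lists of the same size matched on mean intensity in 10 bins.

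Named genes were Gad1, the 10 genes with the largest difference in each direction among those called, for the larval pair the 10 in each direction whose difference exceeded the range of the EC_pos arrays, and from each list the members with the largest differences. The same rule was applied without EC_pos array a and to the contrast with both larval arrays, both added after the values were seen. As exceptions, mira, Nplp2, Pgk, Mcm5, bt, Hsp27 and Hsp68 were named although more than 3 other members of their lists differed more in the comparison described, Mcm5 and bt because they passed the test. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, apart from these additions, the array weights, and the contrasts and list tests without array a that go beyond leaving out each array in turn. List tests against the mean of both larval arrays were also added afterwards. The alternatives were offsets at the 10th and 50th percentile, a floor in place of an offset, no filter or a filter on the mean, quantile normalization, scaling to a common median, eBayes without trend or robust, leaving out each EC_pos array, a pooled-spread contrast and a threshold of 2 log2 units for the larval pair, the mean of a gene's probe sets, and limma's array weights.

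The fits were tested on simulated data with 200 of 9635 probe sets changed in each of 10 runs. All simulated arrays, the larval ones included, were drawn with the means and spread of the EC_pos arrays used. The recovered shares and false calls therefore hold only if larval arrays vary like EC_pos, which was not tested. For EC_pos against LB_pos with all arrays, 0.2% of changes of 1 log2 unit, 0.4% of 2, 40.8% of 4 and 73.8% of 6 units were recovered, with 2.1 false calls per run on average. Without array a the shares were 0%, 13.8%, 72.0% and 82.2%, with 1.2 false calls. For EC_pos against the mean of the larval arrays 0.6%, 16.2%, 64.8% and 85.8% were recovered with all arrays, and 0.6%, 37.6%, 84.8% and 92.2% without array a. For the larval pair, 8 of 200 random lists of 20 genes lay outside the middle 95%, and all 50 lists moved by 1 log2 unit did. These lists held randomly drawn genes, so the check did not cover correlation between the genes of a real list. The slope was recovered with a largest error of 0.00564. Larval arrays had no noise of their own in that simulation, so it did not test noise shared by both axes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.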

Results

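Total RNA from cells of the fruit fly Drosophila melanogaster was measured on 6 one-colour expression arrays. The cells carried a red fluorescent reporter, dsRed1, driven by a 2.1 kb promoter of Gad1, the gene of glutamic acid decarboxylase, which makes the inhibitory transmitter GABA. Cells were separated by fluorescence-activated sorting. The EC_pos group held 4 arrays, a to d, of the fluorescent fraction from cultured embryonic cells. The LB_pos group held 1 array of the fluorescent fraction from the larval brain and ventral nerve cord, and the LB_neg group held 1 array of the non-fluorescent fraction from that tissue. Each array gave 1 intensity for each of 13966 probe sets that were not controls, of which 9635 were bright enough to be tested. Median intensities lay between 181.5 on LB_neg and 229.4 on LB_pos, and the number of arrays limits the precision. The labels do not say whether the 4 EC_pos arrays came from separate cultures, so the p-values below measure only the spread between these arrays, which may be technical. Both larval groups had 1 array and no replicates.

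EC_pos array a stood apart from the other arrays of its group. Over the tested probe sets, log2 intensities of arrays b, c and d correlated pairwise with Pearson's r between 0.908 and 0.944, whereas array a reached r of 0.707 with b, 0.627 with c and 0.588 with d. The 2 larval arrays correlated with r = 0.869. Control probe sets at the 3' and 5' ends of 3 abundant transcripts gave a ratio of 148 for actin, 640.3 for eIF-4a, a translation factor, and 866 for GAPDH, a glycolytic enzyme, on array a. On array c the same ratios were 19.5, 23.6 and 17.7. The highest ratios on any array other than a were 72.5 for actin and 42.4 for GAPDH, both on array b, and 120 for eIF-4a on LB_neg. Hybridization controls also differed, with a geometric mean of 3739 on array a, 1270 (b), 1562 (c) and 1429 (d), 2527 on LB_neg and 7382 on LB_pos. Counts of called probe sets and lists are therefore given with and without array a. This was not done for every median and gene below.

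**Figure D1:**
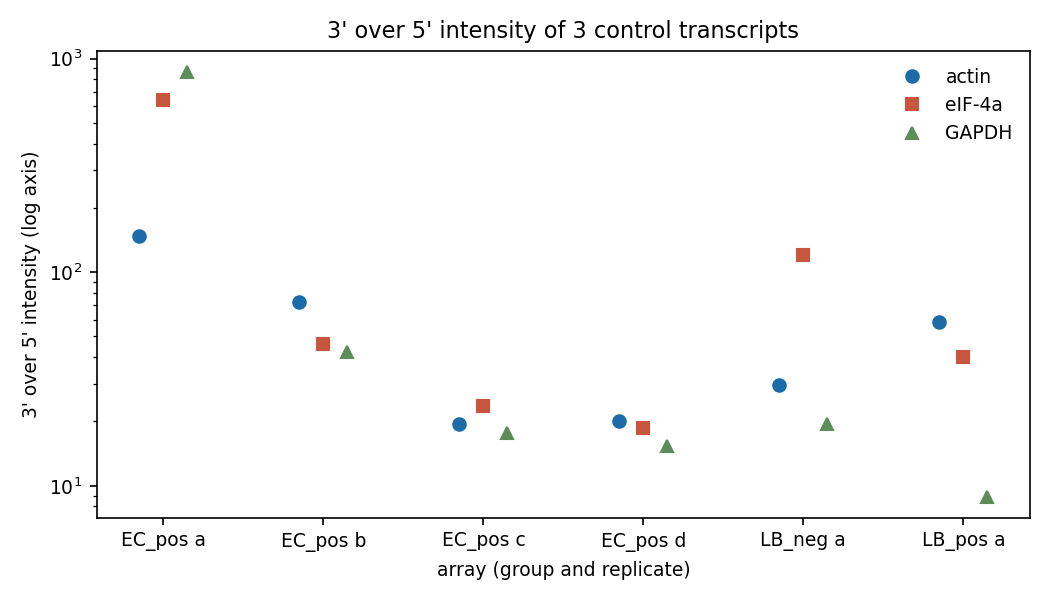
Ratio of the 3' to the 5' control probe set (log axis) for actin, eIF-4a and GAPDH on each of the 6 arrays, 1 point per control and array. Array EC_pos a has the highest ratio of each control, 148, 640.3 and 866, against 20.2, 18.7 and 15.3 on EC_pos d.

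The gene behind the reporter was examined first. The Gad1 probe set, 143478_at, was dim on every array, at 31.5 ± 7.94 in EC_pos (SD, n = 4), 22.0 on LB_neg and 54.8 on LB_pos. On LB_pos it lay just above 53.6, the 25th percentile of all intensities, and on the other arrays below it, so Gad1 did not pass the brightness filter and was not tested. VGAT, which loads GABA into synaptic vesicles, was at 599.975 ± 253 in EC_pos, 739.7 on LB_neg and 737.7 on LB_pos. Gabat, the transaminase that breaks GABA down, was at 706 ± 288 in EC_pos, 576 on LB_neg and 1736 on LB_pos, a larval log2 difference of 1.51. Ssadh, the next enzyme of that pathway, was at 894 ± 185, 979 and 1147. Gat, the plasma membrane GABA transporter, was at 235.7 on array a and between 8.3 and 19.8 on b, c and d, against 10.6 on LB_neg and 9.1 on LB_pos. None of the 4 tested GABA genes differed between EC_pos and LB_pos in limma's test, over all probe sets or adjusted over the list alone, and 0 of them had an unadjusted p under 0.05. The limma adjusted p of Gabat was 0.400. The larval median of the list was 0.11, at percentile 53.7 of 10000 random lists matched for size and brightness, and it was -0.09 with the arrays scaled to a common median.

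The fluorescent and non-fluorescent larval fractions were compared next. Gad1 was too dim to test on both arrays, VGAT was at 739.7 on LB_neg and 737.7 on LB_pos, and the GABA list lay at percentile 53.7 of random lists, so these values showed no enrichment of GABA genes as a group on LB_pos. Genes of neuropeptides, glycolysis, acetylcholine receptors and ion channels were brighter on the LB_pos array, and genes of dividing cells and neural stem cells were brighter on LB_neg. Corazonin (Crz) was at 39.7 on LB_neg and 2022 on LB_pos, a log2 difference of 4.48. Aldolase (Ald1) was at 1719 and 23098, a difference of 3.71, and the GABA receptor subunit Rdl at 300.6 and 5595, a difference of 4.0. The glial determinant gcm went the other way, from 3914 on LB_neg to 499.9 on LB_pos, a difference of -2.84. A difference of at least 1 log2 unit was seen at 1848 probe sets, 1137 higher and 711 lower on LB_pos. Between pairs of EC_pos arrays b, c and d the same count lay between 711 and 1261, and between array a and each of these it was 3814, 4101 and 4502. The split between higher and lower depended on scaling, being 806 and 926 after quantile normalization and 688 and 1358 with a common median. The median over all tested probe sets was 0.11 as deposited, -0.02 after quantile normalization and -0.18 with a common median. A limma contrast that took its spread from the EC_pos arrays called 0 probe sets (306 at an unadjusted p under 0.05), and 23, all higher on LB_pos, without array a. A difference of at least 2 log2 units was seen at 243 probe sets. The hybridization controls of the 2 arrays also differed, at 2527 on LB_neg and 7382 on LB_pos, and whether this affected the comparison was not tested. Percentiles of lists among random lists, here and below, take no account of correlation between the genes of a list.

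Neuropeptide genes were higher on LB_pos as a group. Of 22 tested, 20 were higher on LB_pos, 15 of them by at least 1 log2 unit, and the median difference was 1.87, above all 10000 random lists. Capa, which encodes diuretic peptides, was at 27.3 on LB_neg and 1488 on LB_pos (difference 4.25), allatostatin C (AstC) at 28.2 and 1111 (3.83), and Nplp1, a peptide precursor, at 204 and 2536 (3.33). Nplp2, another precursor, was the 1 member lower by at least 1 unit, at 9370.3 and 4133 (-1.17). The list of peptide processing genes had a median of 1.13 (percentile 99.87), with the amidating enzyme Pal2 at 442 and 4109 and 7B2, a helper of a prohormone convertase, at 1099 and 4927. All 8 tested glycolysis genes were higher on LB_pos, 7 of them by at least 1 unit, and their median of 2.29 was also above all 10000 random lists. Hexokinase A (Hex-A) was at 120 and 1606, Pglym78, a phosphoglycerate mutase, at 1134 and 6950.3, and Pgk, a phosphoglycerate kinase, at 1521 and 2198. On EC_pos array a the glycolysis median lay -1.22 log2 units from the mean of b, c and d, and 1 pair of EC_pos arrays reached an absolute median of 1.83 for this list. LB_neg had a higher 3' to 5' ratio than LB_pos for eIF-4a (120 and 40.1) and GAPDH (19.5 and 8.90), and a lower one for actin (29.5 and 58.3).

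Cholinergic, acetylcholine receptor and monoamine genes were also brighter on the LB_pos array. All 3 tested cholinergic genes were higher by at least 1 unit (median 1.67, percentile 99.76), among them ChAT, which makes acetylcholine, at 938 on LB_neg and 3111 on LB_pos, ChT, the choline transporter, at 396 and 1699, and Ace, acetylcholinesterase, at 111.5 and 306. Of 8 acetylcholine receptor genes, 4 were higher by at least 1 unit and nAChRalpha4 was lower (median 0.94, percentile 99.96). The largest absolute median of this list between any pair of EC_pos arrays was 1.01, above the larval one, and 0.19 among b, c and d. The subunit nAChRalpha3 was at 90.2 and 805, nAChRbeta1 at 168 and 1199, and nAChRalpha4 at 1068 and 482. The median of the 2 tested GABA receptor genes was 2.30 (percentile 99.38), and it lay inside the middle 95% of random lists after quantile normalization, at percentile 94.78 with a median of 0.75 over 3 genes. It was 0.28 over 3 genes with a common median and 0.45 over 6 genes without the filter. Lcch3, the other subunit, was at 1437 and 2212. Monoamine genes had a median of 1.08 (percentile 99.78), with 4 of 6 higher by at least 1 unit, including dopa decarboxylase (Ddc) at 438 and 4586 and the vesicular monoamine transporter (Vmat) at 773 and 3109. Between pairs of EC_pos arrays the absolute monoamine median reached 1.37, above the larval one, and 0.34 among b, c and d. Of 8 glutamate transmission genes, 1 was higher by at least 1 unit, the receptor GluRIA at 365 and 1184 (list median 0.37, percentile 73.27).

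Ion channel genes had a median of 0.82 (percentile 99.95), with 8 of 17 higher by at least 1 unit and 0 lower. The calcium channel Ca-alpha1D was at 298 on LB_neg and 1698 on LB_pos, and the potassium channel slo at 18.9 and 263. General neuron genes were mixed, with 11 of 17 above 0, 4 higher by at least 1 unit and 1 lower (median 0.61, percentile 99.54, and 95.78 after quantile normalization). In that list jeb, a secreted ligand, was at 81.0 and 1118, futsch, a microtubule-associated protein, at 1012 and 2511, and nrv3, a sodium pump subunit of neurons, at 1199 and 3332. The pan-neuronal RNA-binding protein elav was at 4939.9 and 1541, a difference of -1.65. Epidermis, cuticle and trachea genes had a median of 0.70 (percentile 99.4, and 97.18 after quantile normalization), with the chitin deacetylase serp at 36.3 and 276 and the chitin synthase kkv at 42.4 and 306. Between pairs of EC_pos arrays the absolute median of this list reached 1.11, above the larval one, and 0.58 among b, c and d.

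Genes of dividing cells were dimmer on the LB_pos array. Of 24 cell cycle genes, 11 were lower by at least 1 unit and 0 higher, and the median of -0.90 was below all 10000 random lists. The mitotic activator fzy was at 1310.0 on LB_neg and 321 on LB_pos, the kinase aurB at 822 and 265, and the replication licensing factor Mcm5 at 1698 and 596. Neuroblast and progenitor genes had a median of -0.98, also below all 10000 random lists, with 7 of 15 lower by at least 1 unit and 0 higher. The transcription factor cas, which marks late-born neurons, was at 3332 and 559, esg, a progenitor factor, at 1153 and 263, and mira, an adaptor for asymmetric division, at 4453 and 1666. Axon guidance and adhesion genes had a median of -0.62 (percentile 0.01), with 4 of 22 lower by at least 1 unit. These included the receptor unc-5 at 1090.4 and 285, the sorting factor comm at 409 and 132, and the adhesion protein Nrt at 13829 and 6129.9. Between pairs of EC_pos arrays the absolute axon guidance median reached 0.92, larger than the larval one, and 0.53 among b, c and d. Hemocyte and basement membrane genes had a median of -0.35 (percentile 1.98), with 4 of 16 lower and 1 higher by at least 1 unit. PPO1, a prophenoloxidase, was at 288 and 20.1, and Hml, a hemocyte clotting protein, at 746 and 230.2. That list lay inside the middle 95% of random lists when a gene's probe sets were averaged, at percentile 6.38. Its absolute median between pairs of EC_pos arrays reached 1.08, larger than the larval one, and 0.33 among b, c and d.

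By the naming rule, 765 genes were eligible as higher on LB_pos and 563 as lower, each with a larval difference beyond the range of the 4 EC_pos arrays. The 10 with the largest positive differences were CG4577 (5.37), CG12239 (5.20), the lysozyme LysX (4.62), the ribosomal protein gene RpL37-1 (4.48), Crz (4.48), Capa (4.25), the early growth response factor sr (4.12), Rdl (4.0), spab (3.88) and CG42540 (3.86). The 10 with the largest negative differences were insb (-2.91), the general transcription factor Trf (-2.87), gcm (-2.84), CG4935 (-2.72), CG18262 (-2.63), the deubiquitinase Yod1 (-2.57), CG31051 (-2.55), the kinetochore protein Ndc80 (-2.53), the zinc finger factor jim (-2.50) and the planar polarity protein Vang (-2.49). These differences are on the scale of log2(intensity + 53.6), which understates the change of dim genes.

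**Figure D2:**
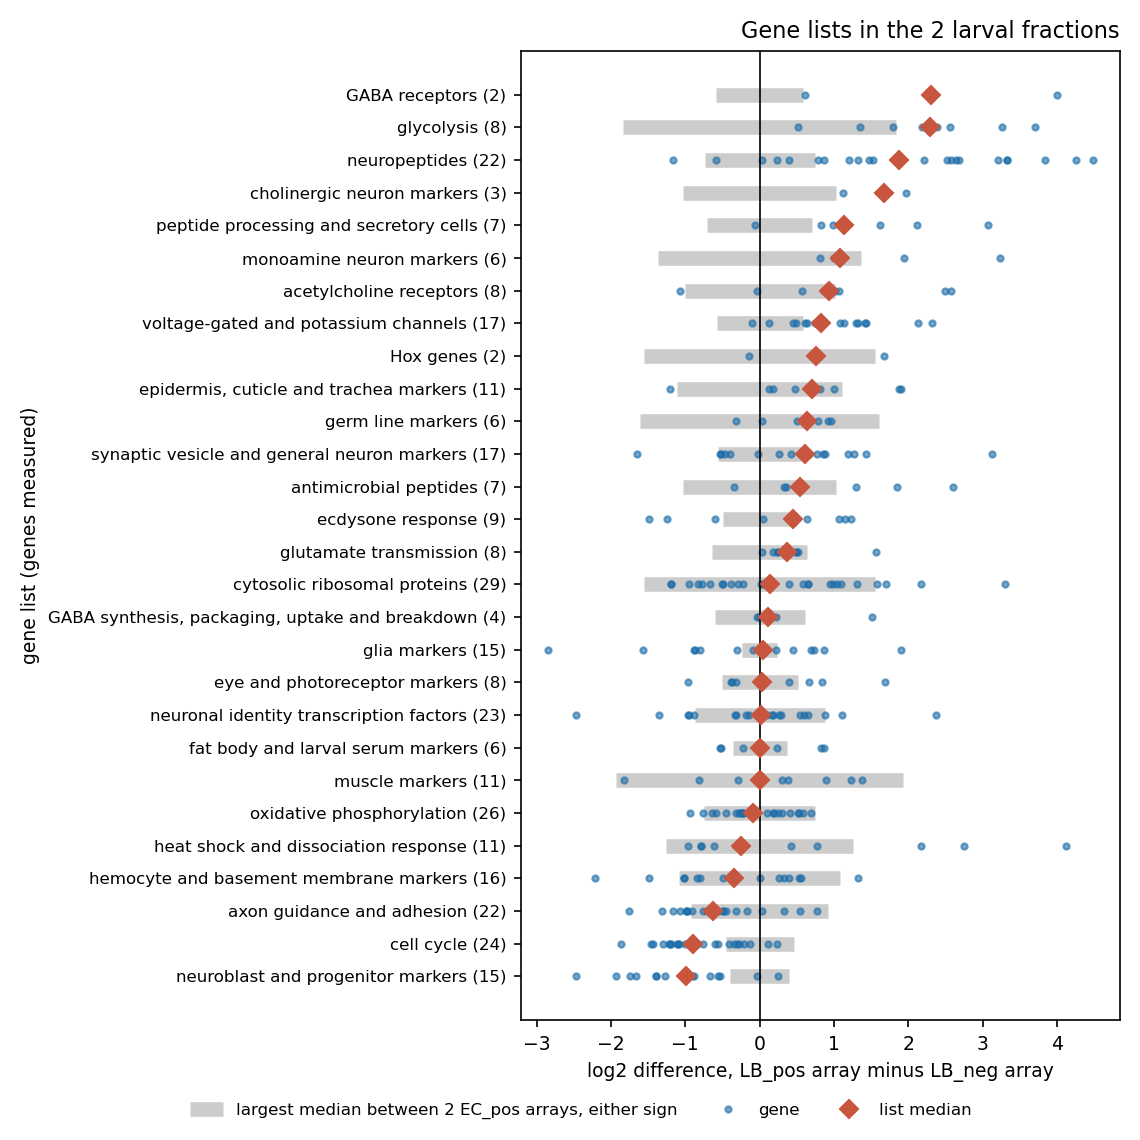
Log2 difference, LB_pos array minus LB_neg array, for the genes (dots) and the median (diamonds) of 28 gene lists, with the number of tested genes after each list name and, as a grey bar, the largest absolute median of that list between any 2 EC_pos arrays drawn on both sides of 0. The neuropeptide and glycolysis medians lie at 1.87 and 2.29, and those of cell cycle and neuroblast genes at -0.90 and -0.98.

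The fluorescent fraction of embryonic culture was compared with that of the larval nervous system to see how cells sorted by 1 reporter differ between these sources. Embryonic or larval origin and culture or tissue differ together between them, so their effects cannot be told apart. No array held a non-fluorescent fraction of the culture. A secreted immune peptide and a membrane protein were far brighter in EC_pos, and an RNA-binding protein of larval neuroblasts was far brighter on LB_pos. IM33, an immune-induced peptide (probe set 145731_at), was at 19089.8 ± 5041 in EC_pos (SD, n = 4) and at 32.9 on LB_pos, a log2 difference of 7.75 ± 0.57 (SE, limma adjusted p = 0.0181). Tsp42Ed, a tetraspanin (146708_at), was at 7910.05 ± 704 against 33.9, a difference of 6.50 ± 0.48 (adjusted p = 0.0181). Syp (153074_at), which times the fates of larval neuroblasts, was at 30.9 ± 13.6 against 4352, a difference of -5.72 ± 0.47 (adjusted p = 0.0256). All 4 EC_pos arrays showed these directions. These 3 probe sets, 2 higher and 1 lower, were those called with all arrays, and 1301 of 9635 passed an unadjusted p under 0.05. The count rested on single arrays. Without array a, 1359 probe sets passed, 830 higher and 529 lower, including the same 3, and without b, c or d limma called 0 each time (866, 780.0 and 818 at an unadjusted p under 0.05). With weights estimated from the spread of each EC_pos array, 0.18 for a and 1.23, 2.03 and 2.22 for b, c and d, 648 passed. LB_pos was 1 array and was assumed to vary like EC_pos.

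Without array a, 730 genes were eligible as higher in EC_pos and 416 as lower, a fit chosen after array a was seen to stand apart. CG34166 differed by 8.62 (limma adjusted p = 1.89e-05 without array a), the cuticle proteins Cpr67B by 7.25 (0.000119) and Cpr47Eb by 6.97 (0.000113), CG17738 by 7.22 (4e-05), and Listericin, an antibacterial peptide, by 7.18 (6.04e-05). With all 4 arrays their adjusted p-values were 0.165, 0.218, 0.123, 0.0723 and 0.0846, and array a was the dimmest EC_pos array for each, at 1232 for CG34166 against at least 26688 on the others. CG13460, CG12310 and CG11370 completed the 10 largest together with IM33 (7.87) and Tsp42Ed (6.49). Among the lower genes Syp (-5.82) was followed by the ecdysone-induced gene ImpE2 (-4.33, adjusted p = 0.000331 without array a), Sidpn, a relative of the neuroblast factor deadpan (-4.31), the juvenile hormone binding protein Jhbp2 (-4.21), the ETS factor Ets65A (-4.08), and the Notch-regulated genes Tom (-3.76) and E(spl)m4-BFM (-3.68). CG42540 (-3.54), the Polycomb group gene Psc (-3.34) and Ypel (-3.27) completed these 10. CG42540 was bright on LB_pos alone, at 1216 against 34 on LB_neg and between 42.7 and 83.2 on the EC_pos arrays. Its place here and among the genes higher on LB_pos than on LB_neg thus rests on the same value. With all arrays the adjusted p of these lower genes other than Syp lay between 0.0784 (Tom) and 0.130 (Psc).

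Muscle and antimicrobial peptide genes were higher as groups in EC_pos than on LB_pos, and cell cycle genes lower, at a preset correlation alone and not with an estimated one (adjusted p = 0.477 with an estimated correlation for each). In limma's camera test with a preset correlation of 0.01, 6 of 28 lists passed, 4 higher and 2 lower, and 9 passed without array a. With an estimated correlation 0 lists passed. With 4 EC_pos arrays limma called 0 members of these 6 lists over all probe sets, so unadjusted counts and counts without array a are given. The muscle list had a median of 2.28 (adjusted p = 8.67e-05, and adjusted p = 0.477 with an estimated correlation). Of 11 members, 5 had an unadjusted p under 0.05, 4 were higher adjusted over the list alone and 8 were higher over all probe sets without array a. The myosin light chain Mlc2 was at 5837 ± 3117 in EC_pos and 32.1 on LB_pos (log2 difference 5.83, adjusted p = 0.104, and 6.41 with 6.04e-05 without array a), and array a, at 1410.2, was the dimmest for it. The muscle median lay -1.94 from that of b, c and d on array a. Antimicrobial peptide genes had a median of 1.85 (adjusted p = 8.67e-05, and adjusted p = 0.477 with an estimated correlation). Of 7 members, 4 had an unadjusted p under 0.05, 4 were higher adjusted over the list alone and 4 over all probe sets without array a. Diptericin B (DptB) was at 13816 ± 1801 against 641 on LB_pos, and Metchnikowin (Mtk) at 4390 ± 1564 against 193. Epidermis, cuticle and trachea genes had a median of 0.98 (adjusted p = 0.0110, and adjusted p = 0.477 with an estimated correlation). Of 11 members, 3 had an unadjusted p under 0.05, 2 were higher adjusted over the list alone and 6 over all probe sets without array a. Hemocyte and basement membrane genes had a median of 0.70 (adjusted p = 0.0127, and adjusted p = 0.477 with an estimated correlation). Of 16 members, 3 had an unadjusted p under 0.05 and 2 were higher adjusted over the list alone. Over all probe sets without array a, 4 of these were higher and 1 was lower. On array a, the epidermis median lay -0.89 and the hemocyte median 0.65 from those of b, c and d.

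Cell cycle genes had a median of -1.26 between EC_pos and LB_pos (adjusted p = 8.67e-05, and adjusted p = 0.477 with an estimated correlation). None of the 24 was called adjusted over the list alone by limma with all arrays, where 9 had an unadjusted p under 0.05, and 15 were lower adjusted over the list alone without array a, 6 of them also over all probe sets. The condensin subunits glu and SMC2 were at 630.4 ± 361 and 366 ± 287 in EC_pos against 2224 and 1418 on LB_pos (adjusted p = 0.00423 and 0.00459 without array a, and 0.320 and 0.343 with it). Acetylcholine receptor genes had a median of -1.21 (adjusted p = 0.0110, and adjusted p = 0.477 with an estimated correlation). None of the 8 was called adjusted over the list alone, 4 had an unadjusted p under 0.05, and, without array a, 3 lower over all probe sets and all 8 adjusted over the list alone. Their median on array a lay 0.93 above that of b, c and d. The 3 further lists that passed without array a were fat body genes, higher with a median of 0.52 (adjusted p = 0.0453), and GABA receptor and general neuron genes, lower with medians of -2.05 and -0.90 (0.0453 and 0.0348). With an estimated correlation none of these 3 passed without array a (adjusted p = 0.547 with an estimated correlation for each). With 4 EC_pos arrays their adjusted p-values were 0.112, 0.292 and 0.0717. For Hox genes, ribosomal proteins, oxidative phosphorylation and glycolysis, median and mean were below 0 while the test, which compares a list with all other genes, pointed up. For axon guidance genes the median was -0.02 and the mean 0.06. None of these 5 lists passed, and each of the 5 medians was above 0 with the arrays scaled to a common median. Array a also set some signs. Without it the medians were 0.17 for ribosomal proteins, 0.23 for oxidative phosphorylation, 0.32 for glycolysis, -0.37 for Hox and -0.31 for axon guidance genes. The median over all tested probe sets was -0.24 as deposited, -0.12 after quantile normalization and -0.01 with a common median, and each of the 6 list medians kept its sign under both.

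**Figure D3:**
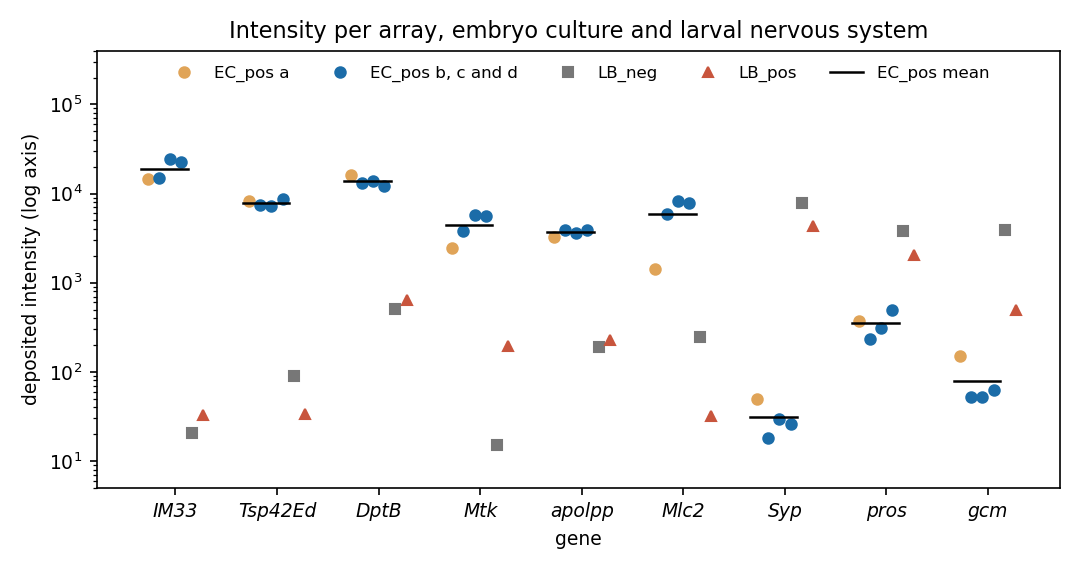
Deposited intensity (log axis) of 9 genes on each array, with EC_pos a, the other EC_pos arrays, LB_neg and LB_pos as separate symbols and the EC_pos mean over 4 arrays as a line. The EC_pos points of IM33 lie between 14609.6 and 24353 against 20.4 and 32.9 on the larval arrays, and those of Syp between 18.1 and 50 against 7852 and 4352.

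EC_pos was then compared with the mean of both larval arrays. As EC_pos is a fluorescent fraction and LB_neg is not, part of the difference between the larval fractions enters this contrast. The glycolysis median, for example, was -0.03 against LB_pos and 1.07 against the larval mean, and the neuropeptide median -0.31 and 0.44. Without array a the medians against LB_pos were 0.32 for glycolysis and -0.50 for neuropeptides. Antimicrobial, muscle and epidermal lists were higher in EC_pos and neuroblast and cell cycle lists lower at the preset correlation of the list test, and none of these passed with an estimated correlation (lowest adjusted p = 0.273). With limma, 318 of 9635 probe sets passed, 249 higher and 69 lower in EC_pos. Without array a, 2767 passed, 1383 higher and 1384 lower, including all 318. Without b or c limma called 0 (1517 and 1427 at an unadjusted p under 0.05), and without d 44 passed. IM33 (7.86), CG17738 (7.09), CG34166 (7.06), Listericin (6.89), Cpr47Eb (6.40), CG12310 (6.33), CG13460 (6.26), Tsp42Ed (6.14), CG13640 (5.65) and the odorant binding protein Obp56h (5.64) had the largest positive differences among 212 eligible genes, with adjusted p between 0.00327 and 0.0467. The largest negative differences among 58 were those of Syp (-6.14), ImpE2 (-4.40), Ets65A (-3.87), E(spl)m4-BFM (-3.77), Tom (-3.58), gcm (-3.54), Jhbp2 (-3.34), insb (-3.32), Dtg, a target of the growth factor Dpp (-3.14), and the Notch target E(spl)m7-HLH (-3.12), with adjusted p between 0.00327 and 0.0202.

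By list, 6 were higher and 2 lower with the preset correlation. With an estimated correlation 0 lists passed, and the lowest adjusted p was 0.273. Cell cycle genes had a median of -1.72 (adjusted p = 5.1e-08, and adjusted p = 0.273 with an estimated correlation), with 2 of 24 members lower over all probe sets, Mcm5 (-2.0 ± 0.36, SE) and Mcm3 (-2.28 ± 0.44), and 15 lower adjusted over the list alone. Neuroblast genes had a median of -1.53 (adjusted p = 0.000645, and adjusted p = 0.283 with an estimated correlation). Of 15, 5 were lower over all probe sets and 7 adjusted over the list alone. Among them pros, which ends neuroblast self-renewal in daughter cells, was at 354 ± 111 in EC_pos, 3842 on LB_neg and 2054 on LB_pos (-2.85 ± 0.41, adjusted p = 0.0240), and cas, mira and E(spl)mdelta-HLH differed by -2.40, -2.52 and -2.88. Antimicrobial peptide genes had a median of 2.49 (adjusted p = 9.61e-06, and adjusted p = 0.283 with an estimated correlation), with 4 of 7 higher over all probe sets and 4 adjusted over the list alone. DptB differed by 4.47 ± 0.41 (adjusted p = 0.0118), Mtk by 5.02 ± 0.48 (0.0134), the peptidoglycan recognition protein PGRP-SB1 by 4.17 and attacin D (AttD) by 2.49. Muscle genes had a median of 2.51 (adjusted p = 4.82e-05, and adjusted p = 0.524 with an estimated correlation). Adjusted over the list alone, 9 of 11 were higher and 1 was lower, and over all probe sets 4 were higher. Mlc2 (4.92 ± 0.77), Mlc1 (4.0), troponin C TpnC73F (3.14) and the titin relative bt (2.13) were those 4.

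Epidermal genes had a median of 1.33 (adjusted p = 0.00120, and adjusted p = 0.524 with an estimated correlation), with the chitin-binding protein obst-A (2.73) and the apical polarity protein crb (2.49) higher over all probe sets and 4 of 11 higher adjusted over the list alone. Glycolysis genes had a median of 1.07 (adjusted p = 0.00875, and adjusted p = 0.524 with an estimated correlation), with Pfk, phosphofructokinase, called over all probe sets (1.98 ± 0.39, adjusted p = 0.0493) and 1 gene adjusted over the list alone. Hemocyte and basement membrane genes had a median of 0.82 (adjusted p = 0.0351, and adjusted p = 0.524 with an estimated correlation), with the laminin LanB2 (2.30) and the collagen IV chain vkg (2.64) called over all probe sets and 2 of 16 adjusted over the list alone. Neuropeptide genes had a median of 0.44 (adjusted p = 0.0263, and adjusted p = 0.524 with an estimated correlation). Of 22, limma called 0 over all probe sets (6 at an unadjusted p under 0.05) and 1 adjusted over the list alone. Without array a the hemocyte list no longer passed (adjusted p = 0.0788), and 4 others did. These were monoamine (0.0246), fat body (0.0348) and ribosomal protein genes (0.0151), higher, and acetylcholine receptor genes (0.0246), lower. None of these 4 passed without array a with an estimated correlation (adjusted p = 0.607 with an estimated correlation for monoamine genes and 0.556 for the other 3). On array a alone the medians of glycolysis and ribosomal protein genes lay -1.22 and -1.64 from those of b, c and d. The 1 called fat body gene, the lipid carrier apolpp, was at 3668 ± 307 in EC_pos, 188 on LB_neg and 230.5 on LB_pos (3.83 ± 0.36, adjusted p = 0.0134). GTP cyclohydrolase (Pu), of monoamine synthesis, was at 1487 ± 516, 105 and 289 (2.67 ± 0.43, adjusted p = 0.0301). The ecdysone-regulated factor br was at 191 ± 58.6, 2404 and 985 (-2.73 ± 0.38, adjusted p = 0.0229). All 8 list medians kept their sign under both other scalings.

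A last comparison placed each EC_pos array between the 2 larval arrays. The slope, across probe sets, of EC_pos minus the larval mean on LB_pos minus LB_neg would be 0.5 for a profile like LB_pos and -0.5 for one like LB_neg. It was 0.161 for array a, 0.253 for b, 0.314 for c and 0.292 for d, a mean of 0.255 ± 0.068 (SD, n = 4), and 0.286 ± 0.031 without array a. All 4 arrays lay on the LB_pos side of 0. Over probe sets whose mean intensity was above the pooled median the mean slope was 0.375, and after quantile normalization 0.159. No test was made. The 4 slopes share the same 2 larval arrays, and the exact sign-flip test considered for them cannot reach a p of 0.05 with 4 arrays. Noise of the larval arrays enters both axes. If the 2 are equally noisy it draws the slope towards 0, and if not it can also move the slope either way. A slope below 0.5 therefore need not mean a profile unlike LB_pos. With 1 array each the noise could not be examined.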

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

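The tests of 3' bias and of the amount of labelled RNA on array a were chosen only after the result was seen, and the test of cell types on array a before.

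For 120 values, the log2 intensities of the genes named in the text, the position slope, the hybridization controls and 3 control ratios, the 4 EC_pos arrays were compared by the gap between the farthest array and the next as a share of the range (Dixon's ratio, against its 5% critical value for 4 arrays). About 1 in 20 groups passes by chance if values are picked without regard to these arrays. The genes here were named from the same arrays, some because limma called them only without array a. The counts that follow partly reflect that choice and cannot be set against chance. Of the 120, 18 passed, and array a was the far array in 12 of them. Below array b, c and d, array a had Rdl at 217.9 against 1192 or more (ratio 0.939), Ald1 at 1753 against at least 19517 (0.943), jeb at 22.6 against at least 652 (0.992), and CG34166 at 1232 against at least 26688 (0.921). The same side held for Nplp1 (410.9 on a, ratio 0.844), RpL37-1 (2759, ratio 0.845) and Hsp27 (2684, ratio 0.852). Of these genes Rdl, Ald1, jeb, Nplp1 and RpL37-1 were also dimmer on LB_neg than on LB_pos, and CG34166 and Hsp27 were brighter there. Over all tested probe sets LB_neg minus LB_pos correlated with array a minus the mean of b, c and d at r = 0.0787. Whether 1 cause lowered single genes on both arrays was not tested. Array a was the brightest for Gat (235.7, ratio 0.889), nAChRalpha4 (2189, ratio 0.870), gcm (150.6, ratio 0.874), PPO1 (1517, ratio 0.935) and glu (1171, ratio 0.961). In the other 6 array b was far. It was the brightest for Crz (7349 against at most 1712, ratio 0.940), nrv3 (3813 against at most 1395, ratio 0.891), Obp56h (7426 against at most 2240, ratio 0.881), br (279.0, ratio 0.878) and CG42540 (83.2, ratio 0.833), and the dimmest for wor (196.5, ratio 0.842).

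The distance of EC_pos array a from b, c and d was examined with 3 tests. Its 3' to 5' ratio exceeded the highest of the other 5 arrays by 1.03 log2 units for actin, 2.41 for eIF-4a and 4.35 for GAPDH, the smallest excess being 1.03, so a strong 3' bias of its labelled RNA may account for part of the distance. Less labelled RNA stays open, since LB_pos and LB_neg, with hybridization controls of 7382 and 2527 against 3739 on array a and 1270 on array b, its nearest, were apart at 0.485 times as many probe sets as those 2 arrays, but this is a single pair. A lower share of neurons with more of other cell types would raise the lists of those types, yet on array a the muscle median was -1.94 and the epidermis median -0.89 from b, c and d, while hemocyte genes were at 0.65, fat body genes at -0.26, glia at -0.16 and general neuron genes at -0.02. No biological explanation beyond these lists was tested for array a, and a difference between cultures stays open.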

How the results depend on the processing

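Array weights and the contrasts with both larval arrays by list were tests chosen only after the result was seen. For EC_pos against LB_pos, limma called 3 probe sets, and 12 with the offset at the 10th percentile, 0 at the 50th (1400.0 at an unadjusted p under 0.05), 6 without a filter, 7 after quantile normalization, 648 with array weights, and from 0 (without array b, 866 unadjusted) to 1359 (without array a). Against the larval mean the count of 318 became 210 at the 50th percentile, 2028 with array weights, and from 0 (without b, 1517 unadjusted) to 2767 (without a). For LB_pos against LB_neg, 1848 probe sets at least 1 log2 unit apart became 816 at the 50th percentile offset, 1135 with a filter on the mean, 243 at 2 log2 units and 0 in the pooled limma contrast (306 unadjusted). The position of 0.255 became 0.375 with the filter on the mean and 0.159 after quantile normalization. With camera's estimated correlation 0 lists passed instead of 6. Except for array a, the cause was not tested. No paired analysis was possible because the groups share only the letter a. Intensities near background limit the differences of dim genes, Gad1 among them.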

Other observations

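The tests of array bias on glycolysis and neuropeptide genes, its correlation with LB_neg minus LB_pos and the test of differentiated neurons against dividing cells were chosen only after the result was seen, and the other 3 tests below before.

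Genes of the heat shock and dissociation response were split between the larval fractions. The activity-regulated factors sr and Hr38 were brighter on LB_pos, at 216 on LB_neg and 4647 on LB_pos and at 14.8 and 404, as was the co-chaperone stv at 611 and 2924. The chaperones Hsp27, DnaJ-1 and Hsp68 were brighter on LB_neg, at 29927 and 19586, 8761 and 4476, and 5122 and 2932. The list median was -0.26 (percentile 16.7 of 10000 random lists). Hsp27 was at 5452 ± 1879 in EC_pos (SD, n = 4), and against LB_pos its limma adjusted p was 0.34 with all arrays and 0.00576 without array a. In dopamine synthesis, tyrosine hydroxylase (ple) was at 346, 2491, 4074 and 4885 on EC_pos arrays a to d, 46.0 on LB_neg and 145.1 on LB_pos. Its log2 difference from LB_pos was 4.23 without array a (limma adjusted p = 0.000724) and 3.43 with all arrays (adjusted p = 0.349). Ddc was at 9473 ± 4177 in EC_pos, with a log2 difference of 2.54 from the larval mean (adjusted p = 0.0629).

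The remaining lists lay inside the middle 95% of random lists in the larval comparison. Their medians, LB_pos minus LB_neg, were 0.05 for glia (percentile 44.3), 0.54 for antimicrobial peptides (94.73), 0.44 for ecdysone response (85.52, and 98.04 after quantile normalization), 0.64 for germ line (92.75) and 0.76 for the 2 tested Hox genes (87.72). Neuronal identity factors had a median of 0.02 (25.64), eye genes 0.04 (32.96), ribosomal proteins 0.13 (82.84) and oxidative phosphorylation -0.09 (39.2). For muscle and fat body genes the percentiles were 36.34 and 48.21. The signs of several followed the scaling, as with a common median glia were at -0.24, muscle at -0.05, fat body at -0.27, eye at -0.19, identity factors at -0.26 and ribosomal proteins at -0.20, and after quantile normalization oxidative phosphorylation was at 0.01. Between EC_pos and LB_pos 0 members of eye, identity factor, ecdysone, glia, glutamate, peptide processing and heat shock lists were called by limma over all probe sets (2, 2, 2, 3, 2, 1 and 2 at an unadjusted p under 0.05). Their medians were -1.03, -0.64, -0.27, 0.31, -0.51, -0.80 and -1.09, and none of these lists passed the camera test. Without array a the medians, in the same order, were -1.08, -0.92, -0.64, 0.41, -0.53, -1.11 and -0.64. The glutamate median was 0.57 after quantile normalization and 0.51 with a common median, both over 5 genes instead of 8, so scaling and membership changed together. For the heat shock list against the larval mean, the median was -0.29 while the test pointed up.

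Without array a, 1359 probe sets differed between EC_pos and LB_pos. Array a alone against b, c and d gave 2592 calls (1132 higher and 1460 lower), but array a was known to stand apart, so this count does not separate a technical from a biological distance. A bias shared by array a and LB_pos was examined by a correlation, which gives no evidence for it. Array a minus b correlated with LB_pos minus the mean of c and d at r = 0.312 (9.74% of variance, Spearman's rho 0.252), but a positive r arises for any array that lacks the profile common to b, c and d, and LB_neg gave r = 0.314. The control ratios of LB_pos were mixed, with actin (58.3) and eIF-4a (40.1) above c and d but GAPDH (8.90) the lowest of all 6 arrays, so a shared bias and the source of the cells, embryonic culture or larval tissue, both stay open.

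Neuropeptide and glycolysis genes were higher on LB_pos than on LB_neg, and the smaller multiple of a median over the largest absolute median of its list between any 2 EC_pos arrays was 1.25, for glycolysis. On array a the neuropeptide median lay 0.13 from the mean of b, c and d (SE over genes 0.262). Members moved both ways, with NPF at 91.2 against at least 453.9 and CCAP at 874.2 against at most 169.8. What marks array a thus did not shift this list as a group. This cannot show how a bias on either larval array would act, as array a is 1 array of another source. As 1 array cannot tell a bias of the labelled RNA from a difference between cultures, the bias alone was not tested. For glycolysis the median on array a was -1.22 (SE over genes 0.369). Such a shift on LB_pos would lower these genes there, not raise them, but array a cannot show which biases LB_pos carried. The same shift on LB_neg may lower glycolysis genes there and stays open. LB_neg was above LB_pos in the control ratios of eIF-4a and GAPDH but not actin. Over all tested probe sets, LB_neg minus LB_pos correlated with array a minus the mean of b, c and d at r = 0.0787. A gate that enriches differentiated neurons over dividing cells stays open too, as the 5 of 5 lists that moved as it needs were seen before it was proposed and add no support, axon guidance genes were lower and epidermal genes higher, and elav, at -1.65, went the other way. The GABA list of 4 tested genes (percentile 53.7) showed no enrichment as a group, with VGAT at 739.7 on LB_neg and 737.7 on LB_pos. Gabat was at 576 and 1736, untested Gad1 at 22.0 and 54.8, and Gat lay below the offset on both arrays. The list therefore cannot tell whether the gate enriched GABA neurons. With 1 array per fraction a difference between the 2 preparations stays open.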
